A study of Mus musculus with 4 samples.

How the data were processed

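Gene expression was measured on 4 one-colour Agilent mouse microarrays on 1 slide, 1 array for each of 4 groups. The groups were LSK cells (Lineage-negative, c-Kit-positive, Sca-1-positive stem and multipotent progenitor cells) and MEP cells (megakaryocyte and erythroid progenitors), each from mice given either JQ1, an inhibitor of the BET bromodomain proteins, or its solvent DMSO for 2 weeks. Per the labels, 20 ng of total RNA from sorted bone marrow cells was isolated with the RNeasy Plus kit and amplified and labelled with Cy3 by the Low Input Quick Amp method, with a one-colour spike-in mix. How many mice were sorted for each array is not given in the sources used here.

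Per the file headers, the authors extracted the scans with Agilent Feature Extraction 10.7.1.1, protocol GE1_107_Sep09, on array design 028005, with probe positions from the mm9 mouse assembly. The deposited scanner output holds a processed signal per spot as an intensity, after background subtraction with spatial and multiplicative detrending, together with the software's error of that signal, which is also an intensity. It also holds, per the file headers, yes or no marks of other kinds, such as well above background, saturated and outlier, which were used as filters. Each array had 62976 spots and 55681 probes that were not controls. The authors' deposited table of normalized values holds a ratio on the linear scale. Its 75th percentile was 1.00 in every array. The quotient of scanner intensity and table value was checked for probes with a table value above 1. It stayed within 1% of a single constant for at least 99.96% of these on each array. For these brighter probes the table is therefore the processed signal divided by 1 number per array, and dimmer probes were not checked. The tool used for that division is not given in the sources used here. Both sets of values were used.

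From the scanner output, the processed signal of each spot was put on the log2 scale. These log2 values were averaged over the replicate spots of a probe that had no outlier mark, and reduced by the log2 of the array's 75th percentile. The result is the log2 of the deposited intensity relative to the array's 75th percentile. Neither the deposited scanner output nor the table has a column of gene symbols, so probes were named through their transcript accessions and the RefSeq annotation of the GRCm38.p6 assembly. Of the 55681 probes, 28026 (50.3%) received a single symbol and 27655 received none. Because the array was designed on mm9 and the annotation is on GRCm38.p6, genes are given by symbol and no positions are printed. Each gene was represented by its brightest probe over the 4 arrays. A gene counted as measured in a comparison when that probe was well above background and carried no outlier mark on both arrays, and as higher or lower when the log2 difference was at least 1, which is 2-fold. A gene above background on only 1 of the arrays was counted separately, with a bound of its fold. For the other array, the bound took the larger of the probe's own reading and the lowest signal of any probe well above background there. The detection limit of a given probe may lie higher, so the true fold may be smaller than the bound.

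The comparisons were JQ1 against DMSO in LSK, JQ1 against DMSO in MEP, MEP against LSK under DMSO, and MEP against LSK under JQ1. The JQ1 differences in LSK and MEP were then compared across genes. With 1 array per group there is no test and no p-value, and no difference below has a replicate check. The spread between different probes of the same gene was used as a measure of array error. It was 0.26 log2 (SD of the difference) for JQ1 against DMSO in LSK, 0.39 in MEP, 0.37 for MEP against LSK under DMSO and 0.27 under JQ1. This covers error that differs between probes of the same gene on this slide. It does not cover mice or sorts, nor any error of RNA isolation, amplification or labelling that a gene's probes share. The median error given by the scanner software was near 10.1% of the signal per spot, and replicate spots had an SD of 0.10 to 0.12 log2. No spot was saturated.

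Because the median measured gene differed between arrays after scaling (below), the value of each gene and list is given relative to the median measured gene of its comparison. This centring was chosen after the data were seen. Counts of genes over a whole comparison, and of genes shared by both cell types, use the differences before centring, whereas counts within a list use centred values. Such values stay as they are when an array is rescaled by a single number. Before the data were examined, 24 gene lists were fixed, covering BET proteins and P-TEFb control, histones, Myc and ribosome biogenesis, STAT5 and JAK-STAT feedback, Polycomb group components, Polycomb-repressed developmental genes, inflammation, TGF-beta and fibrosis, interferon response, mitosis, DNA replication, 7 sets of lineage or cell type markers (erythroid, megakaryocytic, stem and multipotent progenitor, granulocytic and monocytic, lymphoid, mast cell with basophil and eosinophil, stromal and endothelial), immediate early and heat shock genes, p53 targets, cholesterol, lysosome, ribosomal proteins and glycolysis. For each list the median over measured members was placed among the medians of 10000 random lists of the same size, matched on mean expression in 10 bins. A list is called outside when its median lay beyond the central 95% of these. This describes where a list stands on these arrays and is not a significance test. Another 8 lists were written after the data were seen. They are described and used in tests in the closing section, and elsewhere serve only to group genes in figures and to count B-lineage genes shared by both cell types.

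The genes named were chosen by a rule fixed before the data were examined. They are 14 genes of interest to the question, the 10 highest and 10 lowest genes of each JQ1 comparison, 4 bounds each way, 6 genes shared by both cell types each way, 3 genes with the largest difference between cell types each way, up to 4 members of each list per comparison, and the 5 highest and 5 lowest genes of each cell type comparison. Genes with several usable probes entered the highest and lowest only where these pointed the same way, and clone, accession and predicted names were passed over. The rule gave 316 genes, some of which are not reported here. Any other gene named is said to have been chosen after its values were seen. Members of families with near-identical sequences (kallikreins, globins, histones, Ly6 genes, Vpreb genes, Ly49 receptors, mast cell proteases) may share a probe's signal, so their identity is uncertain.

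Alternatives fixed before the data were examined were quantile normalization, scaling to the median, scaling to the spike-in probes, normexp background correction, the authors' deposited values, the mean over a gene's probes, no background filter, genes above the median signal only, and a 1.5-fold threshold. Normexp used an offset of 50 and the median spot signal, because the mean signal planned for it is not a column of the output used here. For the spike-in scaling, 8 of the 10 E1A spike-in probes were above background on all arrays. The procedure was tested on simulated data with 200 changed genes and the probe spread above, set alike for every gene. It recovered 96% of the differences of 1.5 log2 in LSK and 88% in MEP, with 0 false calls in LSK and 136 in MEP, and a planted list reached percentile 100. The real spread was larger among the dimmest genes (0.37 log2 in LSK and 0.50 in MEP), so the simulation does not give the rate of false calls among these. Of 40 random lists, 2 were called outside in LSK and 0 in MEP. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for normexp.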

Results

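Bone marrow carrying the JAK2 V617F mutation, which drives myeloproliferative neoplasms, and a floxed Ezh2 gene with an inducible Cre recombinase was transplanted into lethally irradiated wild-type recipients marked by CD45.1. After Ezh2, the histone methyltransferase of Polycomb repressive complex 2, had been deleted, the mice received JQ1 or DMSO for 2 weeks, and LSK and MEP cells were sorted directly afterwards. Each of the 4 groups (DMSO LSK, JQ1 LSK, DMSO MEP, JQ1 MEP) has 1 array. The number of probes well above background was 25381 (45.6%) on the DMSO LSK array, 26365 (47.4%) on JQ1 LSK, 29605 (53.2%) on DMSO MEP and 25164 (45.2%) on JQ1 MEP. Their 75th percentile signals were 210, 245, 327 and 233.

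The DMSO MEP array stood apart from the other three arrays. Across 23013 probes the LSK arrays correlated at 0.991 with each other, and JQ1 MEP correlated at 0.979 with DMSO LSK and 0.982 with JQ1 LSK. The DMSO MEP array correlated at 0.973 with DMSO LSK, 0.974 with JQ1 LSK and 0.976 with JQ1 MEP. It is the only DMSO MEP array, so no comparison that needs it can be made without it. With 1 array per group no difference below can be set against the spread between replicates, and a gene called higher or lower is one that differed by 2-fold or more.

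Ezh2 itself read alike on the 4 arrays, at 3.36 (DMSO LSK), 3.42 (JQ1 LSK), 3.31 (DMSO MEP) and 3.69 (JQ1 MEP) log2 units above the 75th percentile. Where its probe lies relative to the deleted exons is not known here, so this level says nothing about the deletion. Myc, a gene often repressed by BET inhibition, read 4.17 and 4.35 in LSK and 3.86 and 4.35 in MEP under DMSO and JQ1.

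The first comparison asks what the JQ1 course did in LSK cells. The lymphoid genes had the lowest median of the 24 fixed lists, with 13 of 23 measured members lower on the JQ1 array by 2-fold relative to the median gene. The surrogate light chain gene Igll1 was 5.91-fold lower, the adaptor Blnk 5.75-fold lower, the recombinase gene Rag1 5.4-fold lower and the transcription factor Ebf1 5.09-fold lower. Genes of stem and multipotent progenitor cells were higher, led by Hlf (2.26-fold) and Mecom (2.04-fold). Of the granulocytic and monocytic genes 21 of 26 lay below the median gene, and of the inflammatory genes 18 of 22, but S100a8 and S100a9, the alarmins made by myeloid cells, were 1.97-fold and 2.77-fold higher. Of 12327 measured genes, before centring, 79 were higher and 357 lower by at least 2-fold, and 132 and 270 more were higher or lower by their bounds.

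Of the 24 fixed lists, 12 had medians outside the range of random lists in LSK. The lymphoid list had the lowest median, -1.51 log2 over 23 measured genes, with 13 lower by 2-fold and 0 higher. Over 8 alternatives of processing its median ranged from -1.51 to -0.74 and stayed outside the range in all of them. Among these, scaling to the median and to spike-in probes could not change a centred median, and the deposited values hardly could. The granulocytic and monocytic list had a median of -0.51, with 7 of 26 lower and 2 higher. Its lower members included F13a1 (-2.33), the macrophage colony-stimulating factor receptor Csf1r (-1.60, although its 3 probes ranged from -1.80 to -0.09 before centring), Ly6c1 (-1.19) and neutrophil elastase Elane (-1.09). Its higher members were the neutrophil granule peptide Camp (1.91) and S100a9 (1.47). Inflammatory genes had a median of -0.44 over 22 genes, with Lcn2 at -1.05 and the chemokines Ccl3, Ccl5 and Cxcl10 each at -0.94.

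Stem and multipotent progenitor genes were the only fixed list outside the range on the higher side in LSK, with a median of 0.27 over 29 genes, of which 22 lay above the median gene. Besides Hlf (1.18) and Mecom (1.03), Slamf1 read 0.94, Angpt1 0.86 and Esam 0.64. The megakaryocytic list had a median of -0.26, with Cd226 (-2.43), von Willebrand factor Vwf (-1.47), platelet factor 4 Pf4 (-1.24) and Gp1bb (-1.04) lower and Mmrn1 (1.47) higher among 24 genes. The erythroid list had a median of -0.20 over 22 genes, with Tspo2 (-1.30), carbonic anhydrase Car1 (-1.11) and Ces2g (-1.02) lower and Epb42 (1.40) higher. TGF-beta and fibrosis factors had a median of -0.29 over 16 genes, with fibronectin Fn1 at -1.95, Vegfa at -1.32 and Timp3 at -1.22. When only genes above the median signal were kept, these last 3 list medians were 0.0099 (megakaryocytic), 0.0099 (erythroid) and 0.078 (TGF-beta). The erythroid list was also inside the range without the background filter, and the TGF-beta list with the mean over probes.

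Smaller shifts outside the range of random lists were seen for histones (-0.34, 7 genes), mast cell and basophil genes (-0.26, 18 genes), immediate early and heat shock genes (-0.21, 22 genes), interferon response genes (-0.19, 30 genes) and ribosomal proteins (-0.15, 53 genes). Hspa1a, an inducible heat shock protein, was 3.6-fold lower and the interferon-induced Ifi27l2a 3.06-fold lower. Ribosomal proteins were inside the range under quantile normalization. Lists inside the range in LSK were BET proteins and P-TEFb control (0.13), Myc and ribosome biogenesis (0.08), STAT5 and JAK-STAT feedback (0.09), Polycomb group components (0.08), Polycomb-repressed developmental genes (-0.14), mitosis (0.09), DNA replication (0.07), stromal and endothelial (-0.14), p53 targets (-0.02), cholesterol (-0.02), lysosome (0.02) and glycolysis (0.07). Of these, Myc and ribosome biogenesis was outside the range with normexp correction, with the mean over probes and among genes above the median signal, and stromal and endothelial under the last of these. The Polycomb-repressed median covers only 11 of the 32 members on the array. The others were not well above background on both arrays, so it does not describe silent genes or genes switched on or off. Hexim1, a P-TEFb inhibitor that responds to BET inhibitors, read 0.31, Myc 0.12, Hmga2 0.47, Jak2 0.08, Pim1 0.05, Socs2 -0.05, Cish -0.33, Cdkn2a -0.46 and Gata1 -0.23.

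The genes with the largest single differences in LSK were tissue kallikreins, serine proteases of glandular tissue. Klk1b5 was 17.9-fold, Klk1b26 17.3-fold and Klk1 11.1-fold lower, and since these genes are nearly identical in sequence their identity is uncertain. Fxyd6 (7.56-fold), the chemokine Xcl1 (7.21-fold), Scn2a (7.2-fold), the pre-B-cell receptor gene Vpreb3 (6.88-fold), Tmem178 (6.63-fold) and Zfp60 (6.27-fold) were also lower. The highest genes were Zfp607b (6.34-fold), Camp (3.76-fold), Trim69 (3.3-fold), Noto (3.07-fold), Kbtbd12 (3.01-fold), Clec2d (2.96-fold), Lrrc3b (2.93-fold), Mapk12 (2.83-fold) and Tpm2 (2.79-fold). By bounds, Sema3a was 15.0-fold and Lrrc4c 14.8-fold higher, and Fermt2 was 19.1-fold and P3h2 14.9-fold lower. The median measured gene differed by 0.06 log2. The split of 79 higher and 357 lower became 153 and 256 with scaling to the median and 853 and 135 with scaling to spike-in probes, which moved the median gene to 0.26 and 0.63.

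The second comparison asks the same in MEP cells. Immediate early genes, which respond within minutes to stimulation and to handling of cells, were far lower on the JQ1 array. Fosb was 11.7-fold, Atf3 11.1-fold, Nr4a1 7.51-fold and Klf6 6.42-fold lower. Among the 10 lowest genes were also 3 nuclear noncoding RNAs, with Malat1 12.2-fold and Kcnq1ot1 6.83-fold lower and Neat1 at -3.46 log2. Several lymphoid genes were lower here too (Igll1 5.22-fold, Ebf1 4.24-fold), but Rag1 was at -0.21. Erythroid genes were modestly higher, including the master regulator Gata1 (1.65-fold) and alpha globin Hba-a1 (2.73-fold). The beta globin gene Hbb-b1, named after its values were seen, was at 0.02. The immediate early genes and nuclear RNAs named here stood high on the DMSO MEP array, as Malat1 read 5.55 there against 2.62, 2.63 and 2.28 on the DMSO LSK, JQ1 LSK and JQ1 MEP arrays.

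**Figure D1:**
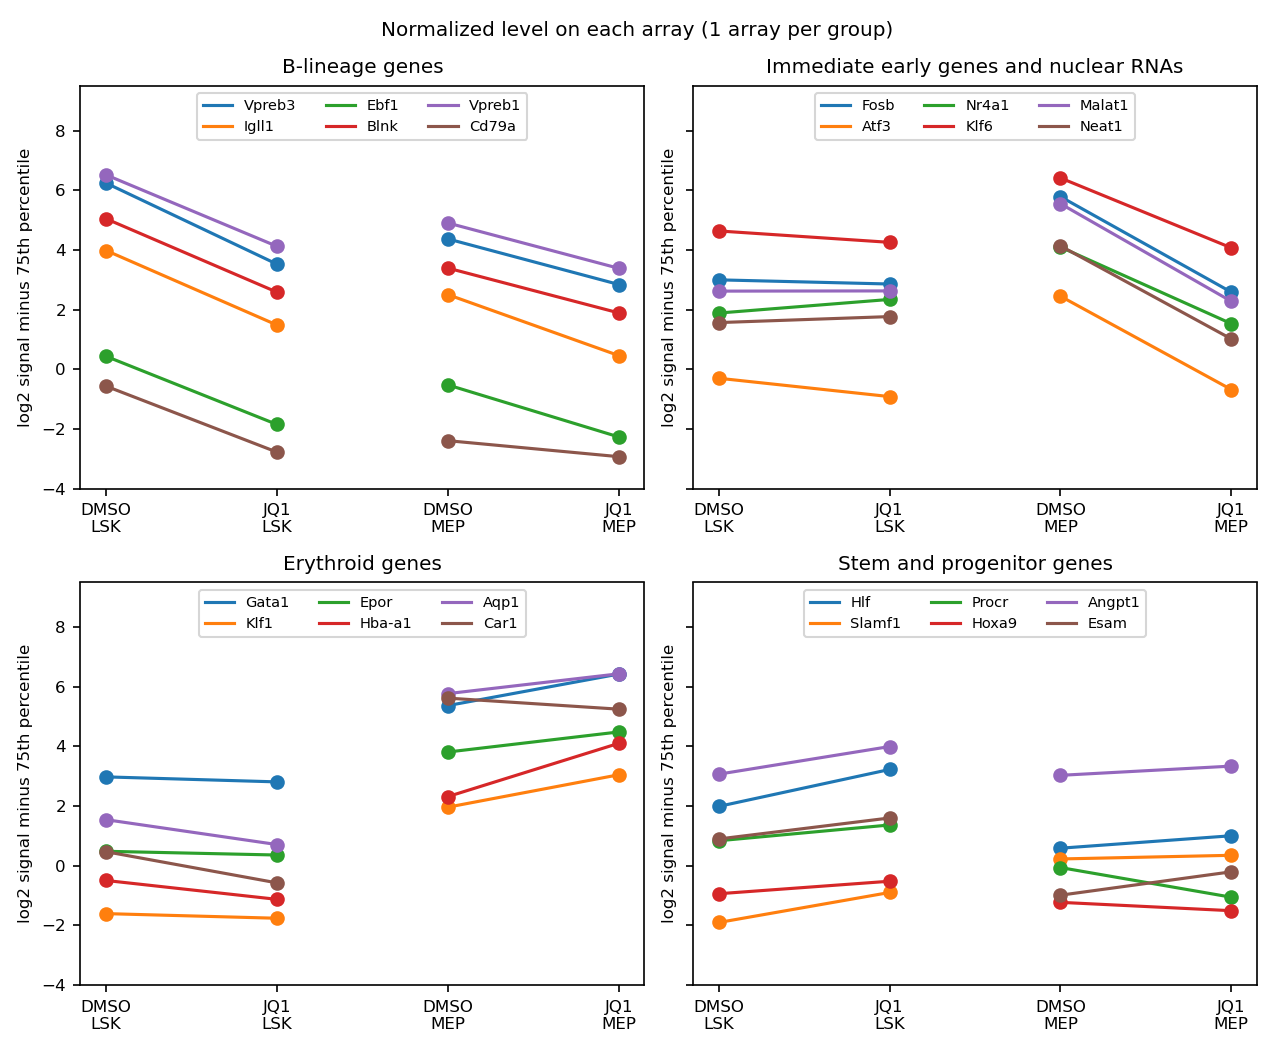
Normalized level (log2 signal minus the array's 75th percentile, y axis) of 24 genes in 4 groups, put together for this plot after the data were seen, on each of the 4 arrays (x axis), with 1 point per array and lines joining DMSO and JQ1 within a cell type; points are filled where the probe was well above background, as all of these were. B-lineage genes such as Igll1 were lower after JQ1 in both cell types, whereas Malat1 was at 5.55 on the DMSO MEP array alone and between 2.28 and 2.63 on the others.

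Of 12549 measured genes in MEP, before centring, 375 were higher and 366 lower by 2-fold or more, with 195 and 205 more by bounds. The median measured gene was itself 0.34 log2 higher on the JQ1 array, and relative to it 123 genes were higher and 724 lower. Of the 24 lists, 10 were outside the range of random lists. The immediate early and heat shock list had a median of -1.60, with 17 of 22 genes lower by 2-fold and 0 higher. Inflammatory genes had a median of -0.86, with 9 of 23 lower, among them the NF-kappaB regulator Nfkbiz (-2.16), Ccl3 (-2.14), Cxcl10 (-2.10) and Ccl2 (-1.64). The lymphoid list had a median of -0.58, with 7 of 24 lower, and Vpreb1 at -1.86. Among genes above the median signal only, the inflammatory and lymphoid medians were -0.10 and -0.15 and lay inside the range.

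Erythroid genes had a median of 0.33 over 29 measured members. Relative to the median gene, itself higher, only 1 reached 2-fold, Hba-a1 (1.45, one of a globin pair its probe may not tell apart). Above the median gene lay 23, among them Rhd (0.85), Cldn13 (0.85) and Gata1 (0.72), and 6 lay below it, among them Car1 (-0.71). The beta globin genes Hbb-bt and Hbb-b1, named after their values were seen, read 0.68 and 0.02. The megakaryocytic list, the other lineage of MEP cells, had a median of 0.01 over 26 genes, with integrin beta 3 Itgb3 at 1.14 and Cd226 at -1.28. Myc and ribosome biogenesis genes had a median of 0.31, with 26 of 28 above the median gene and none 2-fold above it, led by Ddx21 (0.74), Nolc1 (0.65) and Ppat (0.63). Glycolysis genes had a median of 0.27 over 23 genes, with Slc16a3 at 0.85, Aldoa at 0.73 and Tpi1 at 0.64.

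Interferon response genes were lower in MEP (median -0.35 over 28 genes, 4 of them lower by 2-fold), including Oas2 (-1.74), Ifi27l2a (-1.32), Ifi44 (-1.01) and Irf1 (-1.01). Mast cell and basophil genes had a median of -0.40 over 17 genes, although the mast cell proteases Tpsb2 (2.88-fold lower) and Mcpt4 (2.3-fold higher) went opposite ways. Histones had a median of -0.49 over 7 genes, with H4c8 at -1.37 and H1f0 at -1.07, and were inside the range under quantile normalization, normexp correction and among genes above the median signal. The stem and multipotent progenitor list had a median of -0.19 over 28 genes, with Procr at -1.33 and Tcf15 at 0.88, and was inside the range with the mean over probes and without the background filter. Lists inside the range were BET proteins and P-TEFb control (0.20), STAT5 and JAK-STAT feedback (-0.05), Polycomb group components (-0.03), Polycomb-repressed developmental genes (-0.38), TGF-beta and fibrosis (0.01), mitosis (0.19), DNA replication (0.21), granulocytic and monocytic (0.04), stromal and endothelial (0.04), p53 targets (0.10), cholesterol (0.16), lysosome (-0.04) and ribosomal proteins (0.08). Among genes above the median signal, cholesterol, DNA replication and p53 targets were outside it. So were cholesterol and mitosis under quantile normalization, cholesterol and STAT5 feedback with the mean over probes, and DNA replication without the background filter. The Polycomb-repressed median rests on 13 of the 32 members on the array here, and on 11 in each comparison of MEP against LSK below.

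Single members of those lists stood out nonetheless. The cell cycle inhibitors Cdkn2a and Cdkn2b, both Polycomb targets, read 1.23 and 1.03, and Igf2bp3 read 1.36. The granule gene Fcnb read 1.95 and Elane 1.40. The STAT5 targets Pim1, Socs2 and Cish read -1.17, -0.66 and 0.36. Smad6 read -2.26, Phf1 -1.53 and Bmp2 -1.30. Hexim1 was at -0.34, Hmga2 at -0.77, Myc at 0.14, Jak2 at -0.01 and Ezh2 at 0.04.

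The highest genes in MEP were the erythroid adhesion molecule Bcam (6.93-fold), Aoc1 (6.63-fold), Fabp6 (6.38-fold), Vat1l (6.26-fold), Tnni1 (5.24-fold), Coq3 (4.97-fold), Spon2 (4.72-fold), Prl3a1 (4.62-fold), Zp1 (4.57-fold) and Pdcd1 (4.5-fold). Among the lowest were also the NF-kappaB inhibitor Tnfaip3 (8.01-fold), Slc2a4rg-ps (7.5-fold), Mss51 (7.2-fold) and Igflr1 (6.75-fold). By bounds Masp1 was 105-fold higher, Speer4b 18.1-fold higher and Olfr1122 17.2-fold lower, and the true folds may be smaller. The split of 375 and 366 depended on scaling: it was 3039 and 172 with scaling to the median, where the median gene lay at 0.75, and 35 and 2205 with spike-in scaling, where it lay at -0.53.

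**Figure D2:**
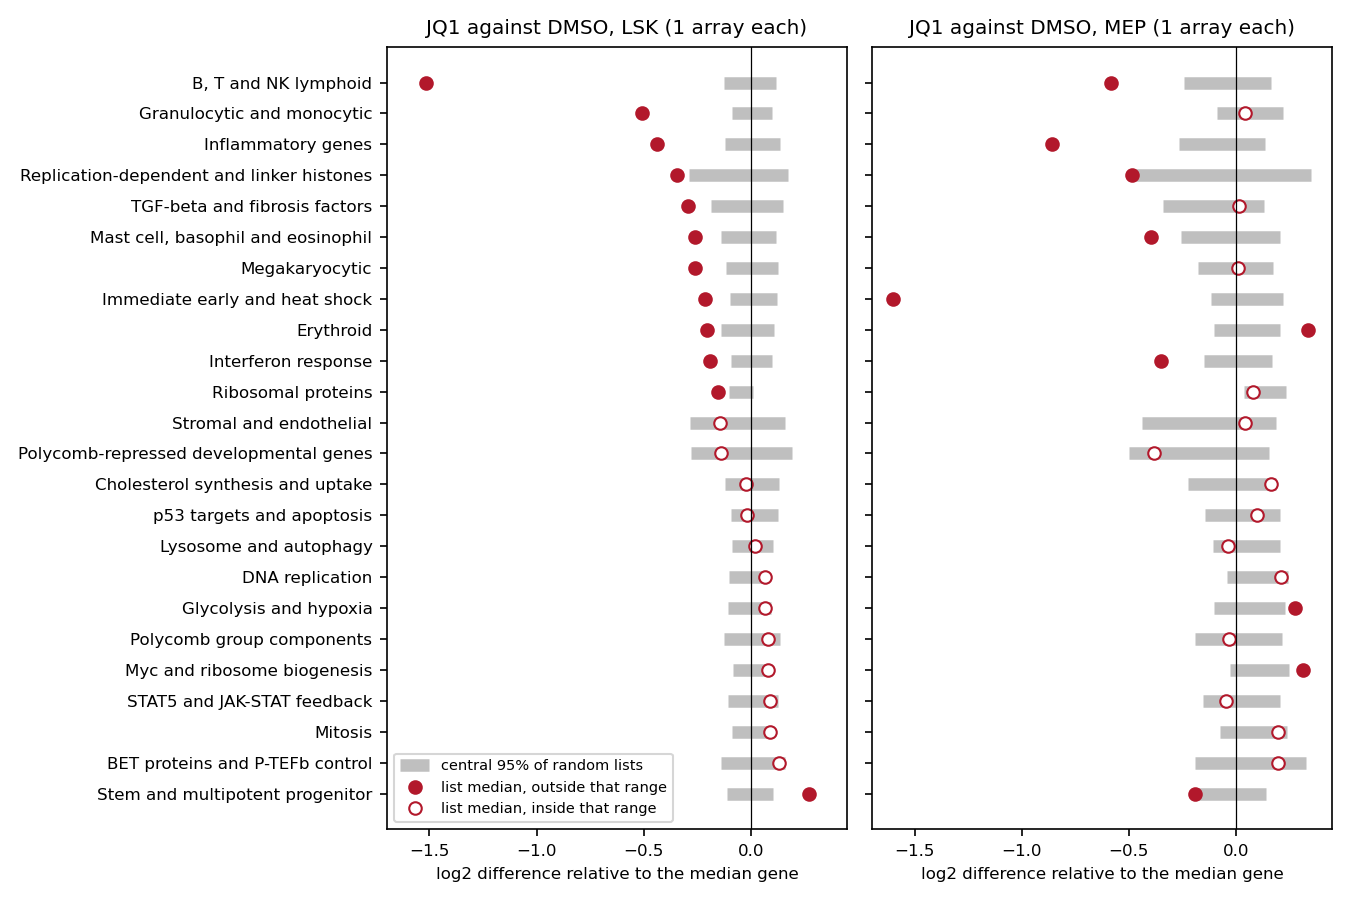
Median log2 difference between the JQ1 and DMSO arrays, relative to the median measured gene (x axis), of the 24 fixed gene lists (y axis) in LSK (left) and MEP (right), 1 array per group; filled points lie outside and open points inside the grey bar, the central 95% of random lists matched on expression. In LSK the lymphoid list lies lowest at -1.51 and the stem list highest at 0.27, and in MEP immediate early genes lie lowest at -1.60 and erythroid genes highest at 0.33.

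Across 12016 genes measured on all 4 arrays, the JQ1 differences in LSK and MEP were weakly related. Pearson's r was 0.157 and Spearman's rho 0.105 across genes, which are not independent replicates. Without the lymphoid list and the B-lineage genes r was 0.142, and without the background filter it was 0.00016. The pairs of arrays behind these differences share no array but sit on the same slide. At 2-fold before centring, 45 genes were lower in both cell types where 8.84 would fall there if the gene sets were independent, and 8 were higher in both against 1.54. B-lineage genes, a group put together after the data were seen, made up 8 of the 45. Relative to the median gene, Igll1 (-2.56 in LSK, -2.38 in MEP), Xcl1 (-2.85, -2.35), Gpat3 (-2.40, -2.23), Gfra2 (-2.55, -2.11) and Hspa1a (-1.85, -2.57) were lower in both. Higher in both were Esm1 (1.18, 1.30), Wfdc21 (1.24, 1.23), S100a8 (0.98, 0.98), Chil3 (1.27, 0.97), the BMP receptor Bmpr1a (1.17, 0.95) and Tff1 (2.38-fold, 1.73-fold).

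Opposite ways at 2-fold before centring were taken by 15 genes, 13 of them lower in LSK and higher in MEP (7.86 if independent) and 2 the reverse (1.73 if independent). The count of opposite genes was 9 relative to the median gene, 23 under quantile normalization, 27 with scaling to the median and 175 with spike-in scaling, where it exceeded the 83 genes going the same way, against 53 in the values above. Those 2 were 8430431K14Rik and Acrbp, named after their values were seen. The complement gene C3 was 3.01-fold lower in LSK and 2.37-fold higher in MEP. Elane read -1.09 and 1.40, and Ly6c1 read -1.19 and 1.38. Among genes named by the rule, MEP minus LSK was highest for Bcam (-0.37 in LSK, 2.79 in MEP), C3 and Trem2 (-2.28, 0.55). It was lowest for Igflr1 (0.81, -2.75), Malat1 (-0.06, -3.61) and Neat1 (0.14, -3.46). By list, the JQ1 difference in MEP minus that in LSK had a median of -1.197 for immediate early genes, -0.46 for stem genes, -0.41 for histones, -0.40 for inflammatory genes, -0.30 for mast cell genes and -0.27 for STAT5 and JAK-STAT feedback. It was 0.24 for megakaryocytic, 0.40 for erythroid, 0.60 for lymphoid and 0.68 for granulocytic and monocytic genes, and these 10 lists lay outside the range of random lists. Every one of these values takes in the DMSO MEP array, which stands apart.

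**Figure D3:**
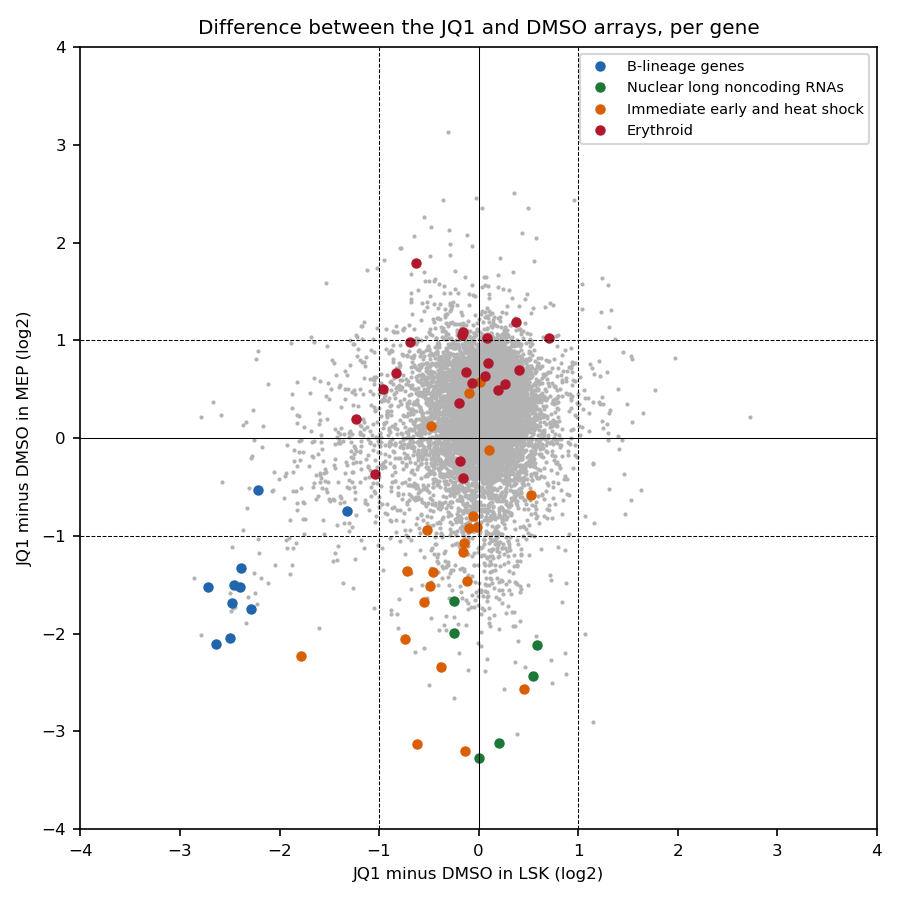
Log2 difference between the JQ1 and DMSO arrays in LSK (x axis) and in MEP (y axis), before centring, for 12016 genes measured on all 4 arrays (grey points), with 4 gene groups coloured (B-lineage genes and nuclear noncoding RNAs were grouped after the data were seen) and dashed lines at 2-fold. B-lineage genes lie at the lower left, with Igll1 lower in both, and the correlation over all genes is 0.157. Nuclear noncoding RNAs and most immediate early genes lie much lower on the MEP axis than on the LSK axis, although the immediate early list was below the range of random lists in LSK too.

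The third comparison, MEP against LSK under DMSO, describes the cell types without the inhibitor. Erythroid genes had a median of 2.16 over 23 genes, 16 of them higher by 2-fold in MEP, including Car1 (41.4-fold), the Rhesus gene Rhd (31.0-fold), the water channel Aqp1 (21.8-fold), Tspo2 (20.3-fold) and Gata1 (6.11-fold). Megakaryocytic genes had a median of 0.74, with 10 of 25 higher, such as Pf4 (14.8-fold), Treml1 (5.32-fold) and Gp5 (4.73-fold). Lower in MEP were Ly6a, which encodes the Sca-1 antigen of the LSK sort (24.0-fold), the lymphoid list (median -1.02, with 13 of 25 lower, among them Dntt at -3.18), the stem list (median -0.30, with 6 of 29 lower, among them Mn1 at -2.14 and Flt3 at -1.71, and Slamf1 at 2.35) and the interferon list (-0.56, with 6 of 30 lower, such as Ifit3 at -2.02). Of 12406 measured genes, before centring, 481 were higher and 910 lower in MEP, with 214 and 310 more by bounds.

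The lowest genes in MEP under DMSO were mast cell proteases, namely Mcpt4 (543-fold lower), Cma2 (83.2-fold) and Tpsb2 (34.6-fold), beside the protease pseudogene Mcpt-ps1 (-6.75 log2) and Rprm (43.5-fold). The mast cell list had a median of -0.31 with 8 of 18 lower and 3 higher. The list left the outside range without the background filter. Sphk1 (30.7-fold), Col5a1 (28.1-fold) and the chemokine Ccl17 (24.0-fold) were among the highest. Immediate early genes were also higher in MEP under DMSO, with a median of 1.43 and 15 of 22 higher by 2-fold, such as Fosb (3.01), Atf3 (2.97) and Nr4a1 (2.43). The neutrophil genes Camp (3.84), S100a9 (3.81) and S100a8 (3.13) were higher as well, although the granulocytic and monocytic list as a whole had a median of -0.29. Other lists outside the range were p53 targets (0.39, 4 of 23 higher), Myc and ribosome biogenesis (0.15, inside the range under quantile normalization), glycolysis (-0.41) and mitosis (-0.38). Inside it were BET proteins (-0.02), histones (0.10), STAT5 feedback (0.07), Polycomb components (-0.00), Polycomb-repressed genes (0.12), inflammatory genes (0.05), TGF-beta (0.02), DNA replication (-0.12), stromal genes (-0.11), cholesterol (-0.10), lysosome (-0.10) and ribosomal proteins (-0.15), of which histones and inflammatory genes were outside it among genes above the median signal. The median gene lay at -0.22, the split relative to it was 705 higher and 536 lower, and with spike-in scaling it was 5302 and 75, with the median gene at 0.91.

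The fourth comparison, MEP against LSK under JQ1, uses neither DMSO array. Erythroid genes were again higher in MEP, with a median of 1.89 and 16 of 21 higher by 2-fold, including Car1 (54.0-fold), Aqp1 (50.5-fold), Tspo2 (44.9-fold) and Gata1 (11.7-fold). Megakaryocytic genes had a median of 0.83, with 9 of 23 higher and 2 lower. Examples were Pf4 (22.1-fold), Vwf (12.5-fold) and Gp1bb (9.83-fold). The stem list had a median of -0.84, with 12 of 27 lower and 2 higher, including Procr (-2.49), Hlf (-2.29) and Mn1 (-2.21), and Ly6a was 17.5-fold lower. Immediate early genes were inside the range of random lists here, with a median of 0.09 and 1 of 22 at 2-fold. Of 12262 measured genes, before centring, 541 were higher and 427 lower, with 294 and 254 more by bounds.

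Granulocytic and monocytic genes were higher in MEP under JQ1, with a median of 0.39 and 7 of 28 higher, such as S100a8 (3.12), S100a9 (2.82), Camp (2.40) and Elane (2.21). Interferon response genes were lower (median -0.76, 9 of 28 lower), with Ifi44 at -2.19 and Oas3 at -1.80. Mcpt4 was 233-fold, Tpsb2 70.6-fold, Cma2 68.7-fold, Chga 21.5-fold and Cma1 21.1-fold lower, and Sphk1 (85.8-fold), the amino acid transporter Slc38a5 (76.8-fold) and Atp1b2 (52.4-fold) were among the highest. Cdkn2a was 5.95-fold higher in MEP. Also outside the range were Myc and ribosome biogenesis (0.31), p53 targets (0.29), cholesterol (0.23), glycolysis (-0.29), mast cell genes (-0.27), lymphoid genes (-0.22), STAT5 feedback (-0.18), lysosome (-0.12) and mitosis (-0.10). Of the STAT5 feedback genes 5 of 21 were lower by 2-fold, among them Dusp6 (-1.74) and Socs3 (-1.53), and 2 were higher. Lysosome was inside the range under quantile normalization, normexp correction and among genes above the median signal, and mitosis under the last of these. Inside the range were BET proteins (-0.14), histones (-0.12), Polycomb components (-0.17), Polycomb-repressed genes (-0.32), inflammatory genes (0.09), TGF-beta (-0.14), DNA replication (0.01), stromal genes (-0.22) and ribosomal proteins (0.02). Polycomb components and inflammatory genes were outside it among genes above the median signal, and stromal genes without the background filter. The median gene lay at 0.07, and the split was 656 and 327 with scaling to the median, where the median gene lay at 0.19, and 340 and 848 with spike-in scaling, where it lay at -0.24.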

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

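With 1 array per group, the differences between cell types in this part were not tested, and no sample could be compared with others of its group. Some genes and lists went one way in LSK and the other way in MEP after JQ1. The JQ1 difference in MEP minus that in LSK, each relative to the median gene, was 2.84 log2 for the complement gene C3, 2.49 for neutrophil elastase Elane, 2.56 for Ly6c1 and 1.87 for the amino acid transporter Slc38a5. All 4 were lower in LSK and higher in MEP. The erythroid list differed by a median of 0.40, being lower in LSK and higher in MEP, and the stem and multipotent progenitor list by -0.46, being higher in LSK and lower in MEP. The LSK side of the erythroid list was 0.0099 among genes above the median signal. All of these take in the DMSO MEP array.

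Probes that the gene comparisons did not use were also counted. Among probes without a gene symbol, 37 were lower by 2-fold or more after JQ1 in both cell types and 3 were higher in both. The numbers that independent sets would give were not computed for these probes, so neither count is read as a change shared by the cell types. In MEP, 1392 of 8023 measured probes without a symbol were lower by 2-fold, before centring, and 223 higher, against 193 and 60 of 8031 in LSK. The MEP numbers rest on the DMSO MEP array, and probes of the same gene disagreed more in comparisons with that array. These are probes for which the annotation used here gave no gene, 689 of the 1392 being designed on genomic intervals. Of the 96 probes for ERCC control transcripts, 3 were above background on at least 1 array and 2 on all arrays.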

How the results depend on the processing

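The counts of genes were recomputed under 9 alternatives fixed beforehand, and relative to the median gene, which was chosen after the data were seen. The correlation, list medians and named genes were recomputed under the 8 alternatives that leave the threshold alone, where these gave a value: keeping genes above the median signal left 606 of 1119 gene values and 90 of 96 list medians. No paired analysis was possible because the labels pair no samples by animal and each group has 1 array, so no array could be left out either. A fit of treatment and cell type together over the 4 arrays, which would take any difference between the cell types in their response as error, was not run. Of 124 alternative values of counts and the correlation, 64 stayed close to the main value (within 1.5 times for a count) and 60 moved. A count has no sign to reverse, but the balance of higher and lower genes turned under spike-in scaling in all 4 comparisons, as did that of genes going the same and opposite ways. Of 8439 values for single genes, 8164 stayed, 275 moved and 0 reversed, and of 762 list medians 726 stayed, 33 moved and 3 reversed. Values relative to the median gene cannot move when an array is rescaled by a single number, so for genes and lists the scaling to the median, spike-in scaling and the deposited values, which are close to such a rescaling, say nothing about stability. Nor do the 2 changes of filter say much for single genes, since they alter only the median that is subtracted. All moved gene values came from normexp correction (218 of 1119), the mean over probes (36) and quantile normalization (21). A gene was called reversed only where its main value was at least 1 log2. A list moved when its call changed, and reversed when it was outside the range of random lists and its sign turned; sign changes of lists inside the range were not counted. The authors' deposited values and the mean over a gene's probes left all 13 counts and correlations close to the main ones. Signal over background limits the dimmest genes: the probe spread among the dimmest LSK genes (lowest of 4 equal groups) was 0.37 log2 against 0.17 among the brightest, and 0.50 against 0.30 in MEP.

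Scaling moved the counts because it shifts every gene of an array alike. With scaling to the median, genes higher in LSK after JQ1 numbered 153, genes higher in MEP 3039 and lower 172, and genes going opposite ways 27. With spike-in scaling the counts of genes higher and lower were 853 and 135 for JQ1 in LSK, 35 and 2205 for JQ1 in MEP, 5302 and 75 for MEP against LSK under DMSO, and 340 and 848 under JQ1, with 83 genes going the same way in both cell types and 175 opposite ways. Relative to the median gene they were 123 and 724 for JQ1 in MEP, with 536 lower for MEP against LSK under DMSO and 9 going opposite ways. Quantile normalization gave 23 going opposite ways, and its cause was not tested.

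Normexp correction also started from the median spot signal and added an offset of 50 to every spot. The arrays' median processed signals were between 14.5 and 27.0, so such a constant shrinks the log2 differences of dim genes. The correction gave 11 higher and 154 lower for JQ1 in LSK and 128 and 166 in MEP. For MEP against LSK it gave 284 and 396 under DMSO and 323 and 200 under JQ1. Genes going the same way numbered 17, and 3 went opposite ways. How much of the move came from the offset was not tested. Without the background filter more genes enter, and the counts were 619 and 1404, 1212 and 1298, 1333 and 2061, and 1516 and 1320 in the same order, with 310 the same way and 248 opposite. The correlation across genes was then 0.00016, and the cause of that drop was not tested. Keeping genes above the median signal leaves fewer genes, and the counts were 7 and 63, 120 and 79, 148 and 265, and 158 and 106, with 6 the same way and 3 opposite. The same restriction reversed the LSK medians of the TGF-beta list (to 0.078), the erythroid list (to 0.0099) and the megakaryocytic list (to 0.0099), and the cause was not tested. A threshold of 1.5-fold, which admits smaller differences, gave 370 and 799, 3063 and 838, 1069 and 2612, and 1245 and 1101, with 209 the same way and 155 opposite.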

Other observations

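The gene groups of the first 2 paragraphs were put together after the data were seen, and the tests of explanations in the later paragraphs were chosen after the result was seen, although the granulocytic, immediate early, erythroid and megakaryocytic lists and quantile normalization were fixed before. Nuclear noncoding RNAs (Malat1, Neat1, Kcnq1ot1 and others) had a median of 0.04 log2 after JQ1 in LSK and -2.61 in MEP, where 6 of 6 were lower by 2-fold. They were higher in MEP than LSK under DMSO (1.99) and lower under JQ1 (-0.64). Of 3765 measured probes designed on genomic intervals without a gene symbol, 689 were lower in MEP by 2-fold before centring and 123 higher. All these MEP values rest on the DMSO MEP array. B-lineage genes had a median of -2.46 in LSK, with 11 of 11 lower, and -1.86 in MEP, with 9 of 10 lower. T and NK cell genes had a median of -0.49 in LSK (3 of 9 lower by 2-fold), also below the range of random lists, and of -0.06 in MEP (0 of 11 lower), inside it. Genes of MHC class II antigen presentation had medians of -0.94 in LSK, with 4 of 9 lower, and -0.65 in MEP, with 1 of 9 lower. Examples in LSK were the invariant chain Cd74 (-1.86), H2-Eb1 (-1.61), H2-Aa (-1.59) and H2-Ab1 (-1.34).

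Ly49 and other lectin-like receptors of NK cells, many of which share much of their sequence, had medians of -2.28 in LSK and -1.80 in MEP, with 4 of 5 lower in each. Tissue kallikreins had a median of -2.92 in LSK, with 4 of 6 lower, and -0.85 in MEP over 3 genes, which was inside the range of random lists. A group of neutrophil genes went the other way. It was put together as secondary granule genes, although it also holds the alarmin gene S100a9. Its medians were 1.24 in LSK, where 4 of 7 were higher and 1 lower, and 0.50 in MEP, where 1 of 9 was higher. Camp (1.91), S100a9 (1.47) and Chil3 (1.27) led the group in LSK. Lcn2, of the granulocytic and monocytic list, read -1.05 in LSK and -0.28 in MEP. The neutrophil group was higher in MEP than in LSK under both DMSO (2.67) and JQ1 (2.02). Endothelial surface genes, several of which stem cells also express, had a median of 0.65 in LSK, with Mmrn1 (1.47) and Esm1 (1.18) at 2-fold, and -0.38 in MEP, with Emcn at -1.72 and Esm1 at 1.30, inside the range.

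B-lineage genes were lower after JQ1 in both cell types, although both sorts select against lineage-marked cells. General carry-over of lineage-positive cells into the DMSO LSK sort would lower genes of other mature lineages too. The granulocytic and monocytic list was lower (median -0.51) while its members S100a9 (1.47) and Camp (1.91) were higher, so this stays open. A smaller share of B-lineage cells in the JQ1 sorts would lower B-lineage genes by a common factor. Their SD was 0.369 in LSK and 0.504 in MEP, against probe SDs of 0.258 and 0.391, but the group was put together after its values were seen and leaves out Rag1 (-2.43 in LSK, -0.21 in MEP), so this decides nothing, and whether JQ1 acted on cell number or on expression stays open.

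Immediate early genes and nuclear noncoding RNAs were lower after JQ1 in MEP. A JQ1 effect of equal size in both cell types would not by itself give a median of -0.21 in LSK and -1.60 in MEP for immediate early genes. Their list was below the range of random lists in LSK too, with 19 of 22 lower. Between MEP and LSK under JQ1 its median was 0.09, inside the range. An equal, smaller effect together with a difference of the DMSO MEP array is therefore not excluded. Linear scaling of arrays with different intensity distributions does not account for the MEP median, since quantile normalization gave -1.76. A technical difference of the DMSO MEP array may contribute, as probes of the same gene disagreed at least 1.33 times as much in the comparisons with that array as in those without it. Handling of that sample, a JQ1 effect confined to MEP and a smaller JQ1 effect in both cell types all stay open, because there is no second DMSO MEP array.

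Erythroid genes were higher after JQ1 in MEP, with a median of 0.33. Fewer cells of the MEP lineages in the DMSO sort would raise megakaryocytic genes by as much. Their median was 0.0097, but single members ranged from -1.28 to 1.14, so this stays open. Carry-over of late, globin-rich erythroid cells was taken to leave the early regulators where they were, but Gata1, Klf1, Epor, Gfi1b and Tal1 had a median of 0.69. This decides nothing, because these genes belong to the erythroid list itself and erythroid cells past the MEP stage may express them too. The globin genes were not alike, with Hba-a1 at 1.45, Hbb-bt at 0.68 and Hbb-b1 at 0.02. Carry-over, an effect of JQ1 on MEP cells and the difference of the DMSO MEP array all stay open, and no test run here separates them.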
